A study of Macaca mulatta and Homo sapiens and Mus musculus with 26 samples.

How the data were processed

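Plasma proteins were measured with the SomaScan assay, in which chemically modified single-stranded DNA aptamers each bind a protein and are then quantified by hybridization fluorescence. The 26 plasma samples came from 4 species, rhesus monkey, human, Sinclair minipig and C57BL6 mouse, each with unirradiated controls and irradiated samples, which made 8 groups. Per the file headers, the authors' table held the fluorescence intensity of each aptamer in relative fluorescence units (RFU), on a linear scale, for 1305 aptamers. The assay's own scaling steps before deposit, and the software used for them, were not given in the sources used here. Median intensities differed between samples, so no common median had been imposed on the deposited values. Of the 1305 aptamers, 50 named several genes (a complex or a family) and 4 named viral targets. The aptamers carry human target names in every species, so a reading in minipig or mouse rests on how well the aptamer binds that species' protein, and levels were never compared between species.

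The authors also deposited 1 table of comparisons per species with a difference, a fold value, a p-value and an adjusted p-value for 1317 targets, of which 12 had no match in the intensity table. Set against the intensities, the deposited group means were a score: the log2 RFU of each sample standardized over all its targets, with r of 1.00 between the authors' and the recomputed means in every species. The authors' deposited fold was therefore 2 raised to a difference of standardized values and not a ratio of RFU. The adjusted p-value deposited by the authors equalled a Benjamini-Hochberg adjustment of their p-value, with a largest difference of 0. The deposited p-values lay close to those of an unequal-variance test on the standardized values, with a median gap of 0.000970 in log10 p in monkey, 0.00208 in human, 0.000723 in minipig and 0.000759 in mouse. The authors' monkey means matched samples 1 to 6 and left out both samples numbered 4 in their groups.

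The analysis used log2(RFU) as deposited, with no filter and no offset. In each species irradiated minus control was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, on that species' samples only, two-sided, with Benjamini-Hochberg adjustment over the 1305 aptamers and a threshold of 0.05. All 26 samples entered a further limma model with 8 group means, from which the mean effect over the 4 species and a moderated F test of unequal effects were taken. Effects were compared between species by Spearman and Pearson correlation across aptamers, with p from 99 regroupings of samples within species plus the real grouping, so that 0.01 was the smallest p possible. A total of 19 lists of proteins, holding 595 gene symbols of which 464 were measured, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

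These tests, the lists, the groups and the rule for naming proteins were fixed before the data were examined. Per species the rule took the 12 highest and 12 lowest log2 fold changes past the threshold, up to 4 members per list by p, proteins called in 2 or more species, the 10 smallest p of each joint test, and a short set of proteins known to respond to irradiation or to sample handling. Where fewer than 10 proteins passed in a species, the 10 smallest p were named as values that did not pass. A protein that the rule named is not reported here. The alternatives were quantile normalization, median centring, an offset of 50 RFU, omission of the dimmest 25% of aptamers, a shared spread over the 8 groups, an intensity trend with robust moderation, a minimum change of 1.5-fold, and omission of each sample. Chosen after seeing the data were the fits without both monkey samples numbered 4, the standardized scale of the authors, and the pair term in the list and joint tests.

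The series design states that monkey samples before and after irradiation were matched by animal, while the labels do not name the pairs. Consecutive sample numbers were therefore checked as pairs. Deviations from the group means correlated at 0.482, 0.486, 0.579 and 0.225 in the 4 pairs, all above the minimum of 0.1, and at most at 0.0312 in any other pairing of a control with an irradiated sample. Of the 24 possible pairings, 1 gave a mean correlation as high (exact p = 0.0417). The numbers were taken to pair the samples, and the result with a pair term stands beside a monkey result where it differed.

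Simulated data had 2-, 4- and 8-fold changes planted in 67, 67 and 66 of the 1305 aptamers, with noise independent between aptamers. The monkey model recovered 58.2%, 89.6% and 95.5%, and the human model 43.3%, 85.1% and 93.9%. The minipig model recovered 32.8%, 86.6% and 92.4%, and the mouse model 52.2%, 94.0% and 97.0%. With no planted change each of these called 0 aptamers. The mean effect recovered 94.0% of the 2-fold changes, with 12 unchanged aptamers among 208 calls. The test of unequal effects recovered 20.9%, 77.6% and 89.4% of changes planted in monkey alone, and 17 of its 142 calls were unchanged aptamers, a share above the 0.05 aimed at. That model shares 1 spread over species whose spreads differ.

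The labels do not say that the human, minipig and mouse samples came from separate individuals, so p-values measure the spread between these samples, which can be technical. The monkey protocol text speaks of 3 animals while 4 control and 4 irradiated monkey samples were present. No 2 samples held identical values, and the highest correlation between 2 samples was 0.986. The number of samples limits the precision, and no counting depth applies to fluorescence.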

Results

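Plasma was profiled in 4 species to compare the protein response to ionizing radiation between animal models and people. The rhesus monkey (nonhuman primate) groups held 4 control and 4 irradiated samples, the latter at about 3.5 Gy by the sample labels and drawn on day 1, while the protocol text gives a somewhat higher dose. The human groups held 3 control samples and 4 samples drawn 6 h after 2 Gy. Sinclair minipig plasma came from 2 control and 2 irradiated samples (3.3 Gy, day 1), and plasma of C57BL6 mice, a common inbred strain, from 5 control and 2 irradiated samples (3.5 Gy, day 1). Dose and time therefore differed along with species. The median signal per sample was 840 to 1086.7 RFU in monkey, 967.7 to 1567.2 RFU in human, 926.1 to 971.1 RFU in minipig and 234.6 to 283.1 RFU in mouse. Mean signals under 100 RFU were found for 55 of the 1305 aptamers in monkey, 3 in human, 90 in minipig and 338 (25.9%) in mouse. Values are geometric means in RFU and log2 fold changes ± SE from limma, with n as above, and p-values are adjusted over the 1305 aptamers.

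In irradiated monkeys the largest fold changes among called proteins were those of creatine kinase, and TNNT2, MDH1, TKT and TPI1 also rose. Creatine kinase M (CKM), the muscle enzyme that regenerates ATP from phosphocreatine, rose from 801 RFU in control plasma to 25989.7 RFU, a log2 fold change of 5.02 ± 0.35 (32.4-fold, adjusted p = 0.000309). The reading for the heterodimer of creatine kinases B and M (CKB/CKM) rose 35.1-fold, by 5.13 ± 0.36 (adjusted p = 0.000309). Cardiac troponin T (TNNT2), a component of the contractile thin filament, rose 6.35-fold, by 2.67 ± 0.53 (adjusted p = 0.0338, and 0.0917 with the pair term). Malate dehydrogenase (MDH1) rose 4.11-fold (2.04 ± 0.18, adjusted p = 0.00138), transketolase (TKT) 3.65-fold (1.87 ± 0.20, adjusted p = 0.00359) and the glycolytic enzyme triosephosphate isomerase (TPI1) 4.91-fold (2.29 ± 0.37, adjusted p = 0.0167). All 4 irradiated samples lay above every control for each of these proteins.

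These 6 readings were the called members of the list of intracellular enzymes and tissue leakage. In it 6 of 36 measured members rose, 0 fell and 30 did not pass. The CKM and CKB/CKM readings both name creatine kinase M, so they may not be independent, which was not analysed here. Adjusted over the list alone, 8 rose and 1 fell. The list lay above the other aptamers in monkey (camera, adjusted p = 0.00165), but the call was lost with an estimated correlation (adjusted p = 0.0967 with an estimated correlation). Its median log2 fold change was 0.64, with 0.69 for the red cell list and 0.70 for the platelet list, which did not pass. Without both samples numbered 4 the medians were 0.64, 0.10 and 0.18, and the leakage list had an adjusted p of 3.16e-05 (0.364 with an estimated correlation). The 18 other lists did not pass in monkey. By fry, which asks whether a list moves on balance 1 way without comparing it with other proteins, 6 lists passed in monkey, 1 in human and 0 in minipig and mouse.

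Histone H2A type 3 (HIST3H2A), a DNA-packaging protein, rose 10.7-fold in monkey plasma (3.41 ± 0.37, adjusted p = 0.00359) and the variant histone H2A.Z (H2AFZ) 8.15-fold (3.03 ± 0.36, adjusted p = 0.00665, and 0.0674 with the pair term). Linker histone H1.2 (HIST1H1C) rose 3.28-fold (1.71 ± 0.23, adjusted p = 0.0095, and 0.0508 with the pair term). The calcium-dependent kinases CAMK2D and CAMK2B rose 4.63-fold and 4.81-fold (adjusted p = 0.0095 and 0.0205, the latter 0.0715 with the pair term). The cytosolic chaperone HSP90 (HSP90AA1/HSP90AB1) rose 2.26-fold (1.18 ± 0.23, adjusted p = 0.0334, and 0.0508 with the pair term).

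Among secreted and receptor proteins of monkey plasma, growth differentiation factor 15 (GDF15), a stress-induced cytokine and p53 target, rose from 629.7 to 4246 RFU, by 2.75 ± 0.34 (6.74-fold, adjusted p = 0.00665). The interleukin-33 receptor IL1RL1 rose 15.3-fold, by 3.94 ± 0.54 (adjusted p = 0.0095, and 0.0508 with the pair term). The T-cell chemoattractant CXCL11 rose 4.83-fold (adjusted p = 0.0167, and 0.0843 with the pair term). The metalloproteinase inhibitor TIMP1 rose 2.88-fold (adjusted p = 0.00665), the protease inhibitor SERPINE2 2.48-fold (adjusted p = 0.0167, and 0.0621 with the pair term) and the neutrophil protease cathepsin G (CTSG) 2.27-fold (adjusted p = 0.0167). The basement membrane protein NID2 rose 2.01-fold, the fungal-glucan receptor CLEC7A 2.19-fold, the phospholipase PLA2G2A 2.28-fold and the lymphocyte surface protein CD48 1.81-fold. With the pair term their adjusted p-values were 0.107, 0.0715, 0.0843 and 0.108.

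In the fit of all monkey samples 4 proteins fell, a number that depended on the fit (31 without both samples numbered 4). The chemokine CCL16 fell from 69692 to 21212 RFU (log2 fold change −1.72 ± 0.36, adjusted p = 0.0416) and the myelin-inhibitor receptor RTN4R from 549 to 215 RFU (−1.36 ± 0.29, adjusted p = 0.0452). The cytokine TWEAK (TNFSF12) fell 2.07-fold (−1.05 ± 0.20, adjusted p = 0.0334) and the appetite peptide AGRP 1.87-fold (−0.90 ± 0.19, adjusted p = 0.0416). None of the 4 passed with the pair term, with adjusted p-values of 0.107, 0.110, 0.108 and 0.0850. The acute-phase protein CRP measured 11872 RFU in controls and 65430.5 RFU after irradiation, by 2.46 ± 0.60, and did not pass (adjusted p = 0.0680). The hematopoietic cytokine FLT3LG measured 545 and 458 RFU (−0.25 ± 0.44, adjusted p = 0.7099).

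In total 48 of 1305 aptamers passed in monkey, 44 higher and 4 lower, and 310 had an unadjusted p under 0.05 (152 higher and 158 lower, and 177 and 203 with the pair term). The pair term left 13 higher and 0 lower, all 13 among the 48, and median centring, which moved the median log2 fold change of all aptamers from 0.01 to −0.13, left 21 higher and 0 lower. Irradiated replicate 4 stood apart: its hemoglobin signal (HBA1/HBB) was 21018 RFU against 138.3 to 286.7 RFU in the 7 other monkey samples, and without both samples numbered 4 the count was 145 (114 higher, 31 lower), 47 of the 48 among them. In those 6 samples PLA2G2A was the call lost (adjusted p = 0.0508), CRP passed (3.30 ± 0.37, adjusted p = 0.00574) and FLT3LG had a log2 fold change of 0.28 ± 0.36. With the pair term the same 6 samples gave 361 calls, 204 higher and 157 lower, a more even split than 44 and 4. The count was 167 without irradiated replicate 4, 14, 12, 13 and 16 without control replicates 1, 2, 3 and 4, and 19 and 16 without irradiated replicates 2 and 3.

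**Figure D1:**
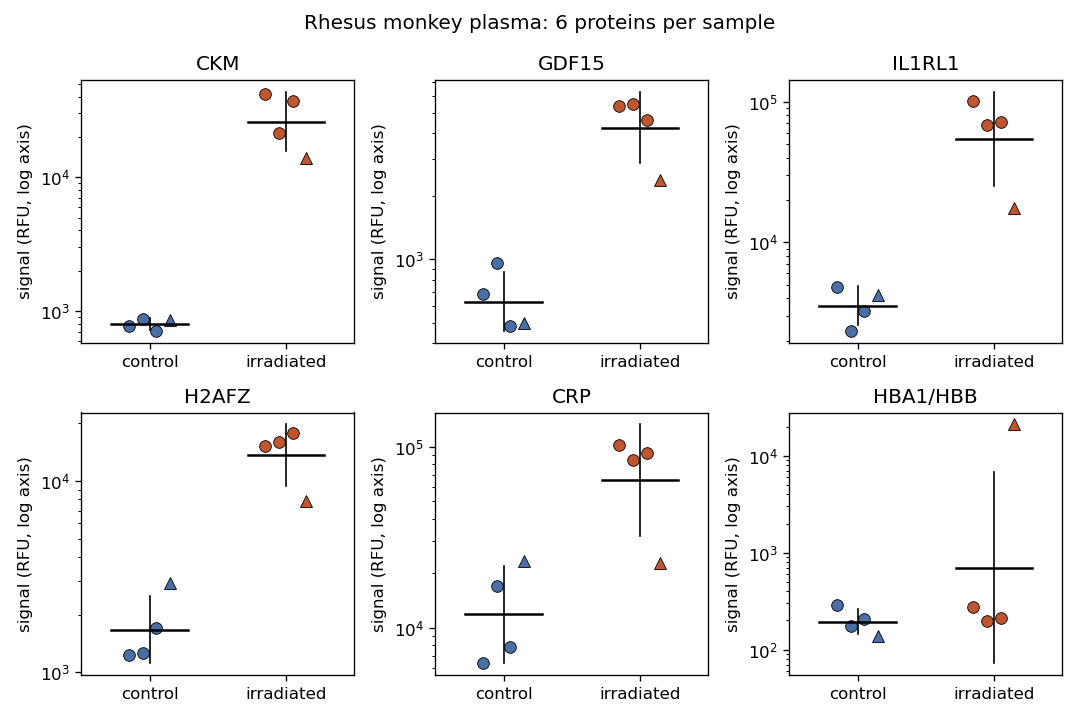
Signal of 6 proteins in monkey plasma in RFU on a log axis, with 4 control and 4 irradiated samples as points, triangles for both samples numbered 4, black lines for geometric means and bars for ±1 SD of log2 values. CKM lay at 711.4 to 875.7 RFU in controls and 13899.8 to 42000.1 RFU after irradiation, while HBA1/HBB was high in irradiated replicate 4 alone.

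In human plasma at 6 h the largest fold changes among called proteins were those of GDF15, CX3CL1, EPO, FTH1/FTL, CST1 and HAMP. The labels do not say whether control and irradiated samples came from the same people. Differences between donors therefore cannot be told apart from irradiation, and rose and fell describe irradiated against control samples. GDF15 rose from 858 to 17005 RFU, by 4.31 ± 0.61 (19.8-fold, adjusted p = 0.0140). The membrane-derived chemokine CX3CL1 rose 14.9-fold, by 3.90 ± 0.45 (adjusted p = 0.0098), and erythropoietin (EPO), the hormone that drives red cell production, 9.92-fold, by 3.31 ± 0.39 (adjusted p = 0.0098). The iron storage protein ferritin (FTH1/FTL) rose 7.95-fold, by 2.99 ± 0.41 (adjusted p = 0.0138), and hepcidin (HAMP), the hormone that blocks iron export, 7.67-fold, by 2.94 ± 0.35 (adjusted p = 0.0098). All 4 irradiated samples lay beyond all 3 controls for every human protein named here as called.

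In human plasma the neutrophil attractant CXCL8 rose 4.59-fold (2.20 ± 0.23, adjusted p = 0.00887), the monocyte attractant CCL2 4.07-fold (2.02 ± 0.31, adjusted p = 0.0191), CXCL10 3.20-fold (1.68 ± 0.22, adjusted p = 0.0128) and CXCL9 3.38-fold (1.76 ± 0.33, adjusted p = 0.0478). The interleukin-18 inhibitor IL18BP rose 2.81-fold (1.49 ± 0.25, adjusted p = 0.0290). In the list of inflammatory cytokines and chemokines 5 of 40 members rose, 0 fell and 35 did not pass, and adjusted over the list alone 6 rose and 1 fell (camera, adjusted p = 0.00705). In the interferon-induced list 3 of 14 rose, 0 fell and 11 did not pass, and adjusted over the list alone 6 rose and 0 fell (camera, adjusted p = 0.00165). CXCL9 and CXCL10 are members of both lists. Neither call held with an estimated correlation (adjusted p = 0.862 with an estimated correlation for each). By fry the interferon-induced list passed (adjusted p = 0.0290) and the inflammatory list did not (adjusted p = 0.183).

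In human plasma lactoferrin (LTF), an iron-binding protein of neutrophil granules, fell from 34720.3 to 6270.45 RFU, a log2 fold change of −2.47 ± 0.21 (5.54-fold lower, adjusted p = 0.00458), and lysozyme (LYZ) 2.40-fold (−1.26 ± 0.22, adjusted p = 0.0368). Granulysin (GNLY) and granzyme A (GZMA), effector proteins of cytotoxic lymphocytes, fell 3.57-fold (−1.84 ± 0.19, adjusted p = 0.00887) and 3.46-fold (−1.79 ± 0.26, adjusted p = 0.0140). The low-affinity IgE receptor of B cells (FCER2) fell 3.93-fold (−1.97 ± 0.31, adjusted p = 0.0207). In the lymphocyte list 0 of 40 members rose, 3 fell and 37 did not pass, and adjusted over the list alone 7 fell (camera, adjusted p = 0.000163). In the neutrophil granule list 0 of 17 rose, 2 fell and 15 did not pass, and adjusted over the list alone 4 fell (camera, adjusted p = 0.0416). Both calls were lost with an estimated correlation (adjusted p = 0.862 with an estimated correlation for each). The neutrophil call was also lost with median centring (adjusted p = 0.0883), with quantile normalization (0.0847), and without control replicate 1 (0.0698), irradiated replicate 3 (0.0684) or irradiated replicate 4 (0.0808). With irradiated replicate 1 left out, 8 lists passed in human in place of 4.

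Further human calls were the secreted cysteine protease inhibitors cystatin SN (CST1), which rose 7.88-fold (2.98 ± 0.47, adjusted p = 0.0207), and cystatin SA (CST2), which rose 5.76-fold (2.53 ± 0.42, adjusted p = 0.0290). Bone sialoprotein (IBSP) rose 4.94-fold (adjusted p = 0.0140), the growth factor carrier IGFBP2 2.94-fold (adjusted p = 0.0468) and the enzyme aminoacylase 1 (ACY1) 2.45-fold (adjusted p = 0.0362). The interleukin-22 antagonist IL22RA2 fell 4.72-fold (−2.24 ± 0.30, adjusted p = 0.0134) and the granulocyte and monocyte peptide resistin (RETN) 4.40-fold (−2.14 ± 0.26, adjusted p = 0.0108). CKM measured 923 RFU in controls and 478 RFU after irradiation (−0.95 ± 0.47, adjusted p = 0.453), and FLT3LG 449 and 454 RFU (0.01 ± 0.29, adjusted p = 0.982).

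In total 23 aptamers passed in human, 16 higher and 7 lower (69.6% higher), and 154 had an unadjusted p under 0.05 (83 higher and 71 lower). The median log2 fold change of all aptamers was 0.11 in human and −0.11 after median centring, and other scalings moved the split to 12 higher and 9 lower (57.1% higher, median centring, 18 of the 23 kept) or 14 and 10 (58.3%, quantile normalization, 19 kept). IL18BP, CST2, ACY1 and CXCL9 did not pass under either scaling, and CCL2 did not pass with median centring (adjusted p = 0.0522). The count was 6 without control replicate 3, 15 without control replicate 1 and 14 without irradiated replicate 4.

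**Figure D2:**
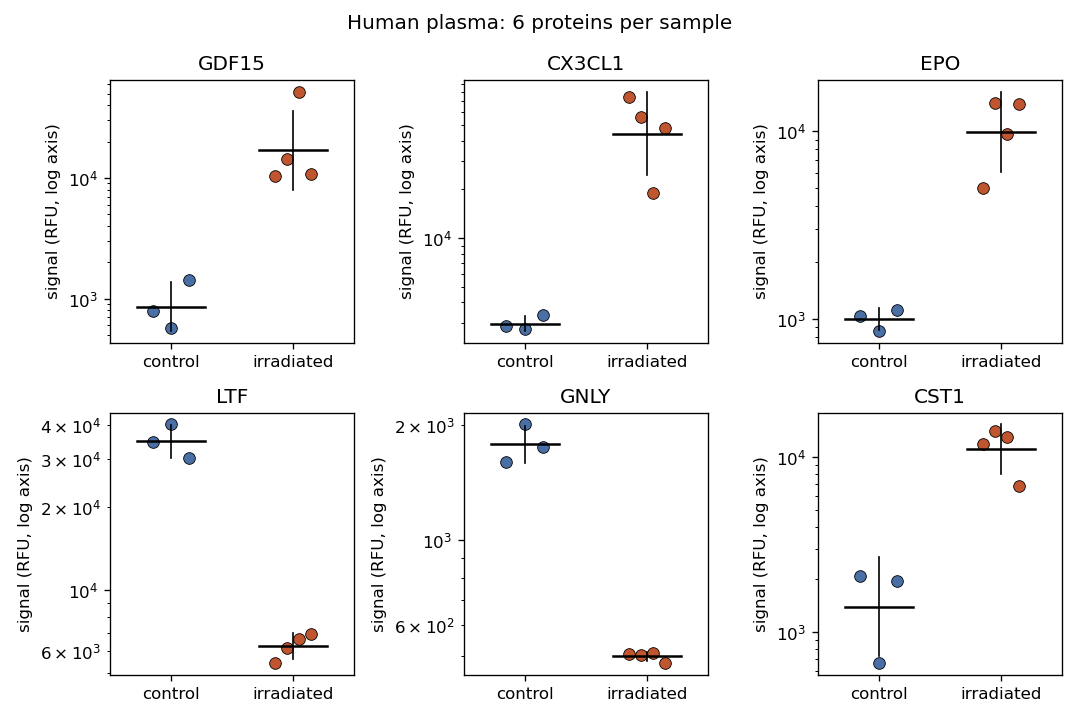
Signal of 6 proteins in human plasma in RFU on a log axis, with 3 control and 4 irradiated samples as points, black lines for geometric means and bars for ±1 SD of log2 values. GDF15 lay at 568.9 to 1422.2 RFU in controls and 10350.7 to 51722.8 RFU after irradiation, and LTF at 30178 to 40035.9 RFU and 5417.8 to 6949.7 RFU.

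In minipig plasma no protein passed the threshold. The smallest p-values belonged to muscle proteins: fast skeletal troponin I (TNNI2) measured 3827 RFU in controls and 31151 RFU after irradiation, a log2 fold change of 3.03 ± 0.23, and TNNT2 1238 and 6887 RFU (2.48 ± 0.19), each with an adjusted p of 0.196. The actin-binding protein transgelin 2 (TAGLN2) measured 5651 and 30671 RFU (2.44 ± 0.38), the phosphodiesterase PDE4D differed by 1.25 ± 0.18, the adhesion molecule ICAM1 by 1.17 ± 0.19 and the cytokine TNFSF15 by −1.22 ± 0.20, each with an adjusted p of 0.823. Parathyroid hormone (PTH) differed by −1.46 ± 0.26 (adjusted p = 0.858) and the beta-endorphin reading (POMC) by −1.01 ± 0.20 (adjusted p = 0.998). GDF15 differed by 0.12 ± 0.27 and CKM by 0.29 ± 0.34. By limma 0 of 1305 aptamers passed and 39 had an unadjusted p under 0.05, 30 of them higher. With the spread shared over the 8 groups 1 passed, TAGLN2. Of the 19 lists 0 passed, and without irradiated replicate 2 the leakage list passed (higher).

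In mouse plasma no protein passed either. The reading for the cell-cycle complex of CDK2 and cyclin A (CDK2/CCNA2) was 439 RFU in controls and 1243 RFU after irradiation (2.83-fold, adjusted p = 0.175), and that for the Wnt-receptor ubiquitin ligase ZNRF3 156 and 522 RFU (1.75 ± 0.29, adjusted p = 0.179). Slow skeletal myosin-binding protein C (MYBPC1) measured 12762 and 1479 RFU (−3.11 ± 0.63), the mitochondrial carrier SLC25A18 differed 2.30-fold and the Wnt inhibitor sclerostin (SOST) 2.76-fold, each with an adjusted p of 0.407. The ribosomal protein RPS3 differed by −1.55 ± 0.38, HIST1H1C by 1.10 ± 0.28 and the lectin FCN1 by 1.49 ± 0.37 (adjusted p = 0.562). GDF15 measured 162 and 182 RFU (0.17 ± 0.36) and CKM differed by −0.47 ± 0.27. By limma 0 of 1305 aptamers passed and 47 had an unadjusted p under 0.05, 23 higher and 24 lower. With the spread shared over the 8 groups 1 passed, CDK2/CCNA2, and without irradiated replicate 2 the count was 4 (FOLH1, MMP10, FCN1 and ZNRF3, of which FOLH1 and MMP10 are named after their values were seen). Of the 19 lists 0 passed, and 1, metabolic and endocrine hormones (lower), passed with median centring, without control replicate 1 or 2, or without irradiated replicate 1.

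The mean effect over the 4 species asked which proteins changed on average, so a large change in a single species can carry a call. An irradiated sample counted as on the side of the change if it lay beyond its species' control mean in the direction of the mean effect, by any margin. GDF15 had the smallest p, with a mean log2 fold change of 1.84 ± 0.25 (adjusted p = 0.000407) and 11 of 12 irradiated samples on the side of the change. It measured 2.75 in monkey, 4.31 in human, 0.12 ± 0.27 in minipig and 0.17 ± 0.36 in mouse, and it did not pass in minipig or mouse. Linker histone HIST1H1C followed at 1.08 ± 0.18 (adjusted p = 0.00244, 11 of 12), with 1.71, 1.12, 0.36 and 1.10 in the same order. The collagen-binding integrin ITGA1/ITGB1 was higher in 12 of 12 irradiated samples, by 1.15 ± 0.21 (adjusted p = 0.00756), with 1.37, 1.65, 0.66 and 0.92 per species. The ectodysplasin receptor EDA2R, a p53 target, rose on average by 0.63 ± 0.12 (adjusted p = 0.00756, 11 of 12). TNNT2 rose on average by 1.37 ± 0.26 (adjusted p = 0.00756), with 2.67, 0.97, 2.48 and −0.64 per species.

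A further 5 proteins were named by the size of p. CX3CL1 rose on average by 1.28 (adjusted p = 0.00933, 9 of 12 samples) and IL1RL1 by 1.26 (adjusted p = 0.0110, 10 of 12, with signals under 100 RFU in minipig and mouse). CDK2/CCNA2 rose on average by 0.63 (adjusted p = 0.0125, 10 of 12), while LTF fell, at −0.76 (adjusted p = 0.0125, 10 of 12). In monkey, human, minipig and mouse CX3CL1 measured 1.15, 3.90, 0.13 and −0.08, and CDK2/CCNA2 0.703, 0.568, −0.273 and 1.502. Tested per species, CX3CL1 and LTF passed in human alone, IL1RL1 in monkey alone and CDK2/CCNA2 in no species. CKM had a mean of 0.97 (adjusted p = 0.0180) with 5 of 12 samples on the side of the change, and 5.02, −0.95, 0.29 and −0.47 per species. In total 20 aptamers passed, 16 higher and 4 lower. The count was 7 without minipig control replicate 1 or without mouse irradiated replicate 2, 11 without minipig control replicate 2 and 10 without minipig irradiated replicate 2.

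Of the lists, 4 passed in the mean effect. Intracellular enzymes and tissue leakage lay higher (3 of 36 rose, 0 fell and 33 did not pass, adjusted over the list alone 5 rose, camera, adjusted p = 0.00333), as did DNA damage and p53 response (1 of 23 rose and 22 did not pass, adjusted over the list alone 1 rose, adjusted p = 0.00682). The 3 leakage members were TNNT2, CKM and CKB/CKM. Of these, CKM and CKB/CKM were called in monkey alone (5.02 and 5.13), with −0.95 and −1.08 in human. Median log2 fold changes of the leakage list were 0.64 in monkey, 0.59 in human, 0.08 in minipig and −0.10 in mouse. Those of the DNA damage list were 0.44, 0.57, 0.06 and −0.003 in the same order. Metabolic and endocrine hormones lay lower (1 of 39 fell and 38 did not pass, adjusted over the list alone 1 fell, adjusted p = 0.00371), as did lymphocyte proteins (0 of 40 passed, adjusted over the list alone 2 fell, adjusted p = 0.0177). The lymphocyte list did not lie lower in monkey. Its median log2 fold change was 0.19 there, −0.24 in human, −0.07 in minipig and −0.13 in mouse, and it passed by camera in human alone. With the pair term 5 lists passed in place of 4. None of the 4 held, with adjusted p = 0.372, 0.372, 0.372 and 0.462 with an estimated correlation. Without minipig irradiated replicate 1 the lymphocyte list had an adjusted p of 0.0501.

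Effects differed between species for 32 aptamers by limma's moderated F test, which called more unchanged proteins on simulated data than the threshold allows. CKM differed most (adjusted p = 3.99e-07), with log2 fold changes of 5.02 in monkey, −0.95 in human, 0.29 in minipig and −0.47 in mouse, followed by CKB/CKM (adjusted p = 3.22e-06). CST1 (adjusted p = 0.000189) measured 2.98 in human and −0.45, −0.03 and 0.40 in monkey, minipig and mouse. IL22RA2 (adjusted p = 0.000320) measured −2.24 in human and 0.27, 0.06 and 0.25 elsewhere, and LTF (adjusted p = 0.00143) −2.47 in human and −0.85, −0.11 and 0.39 elsewhere. IL1RL1 (adjusted p = 0.00109) measured 3.94 in monkey and 1.65 in human, while its signal was 22.2 and 23.0 RFU in minipig and 18.6 and 12.4 RFU in mouse (controls and irradiated), so no change was read from these low signals. GDF15 (adjusted p = 0.00144), HIST3H2A (adjusted p = 0.00206), CX3CL1 and TAGLN2 (adjusted p = 0.00313 each) also differed. Between pairs of species, 35 aptamers differed for monkey and human, 11 for human and mouse, 8 for monkey and mouse, 7 for human and minipig and 5 for monkey and minipig. For minipig and mouse limma called 0, with 32 at an unadjusted p under 0.05.

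**Figure D3:**
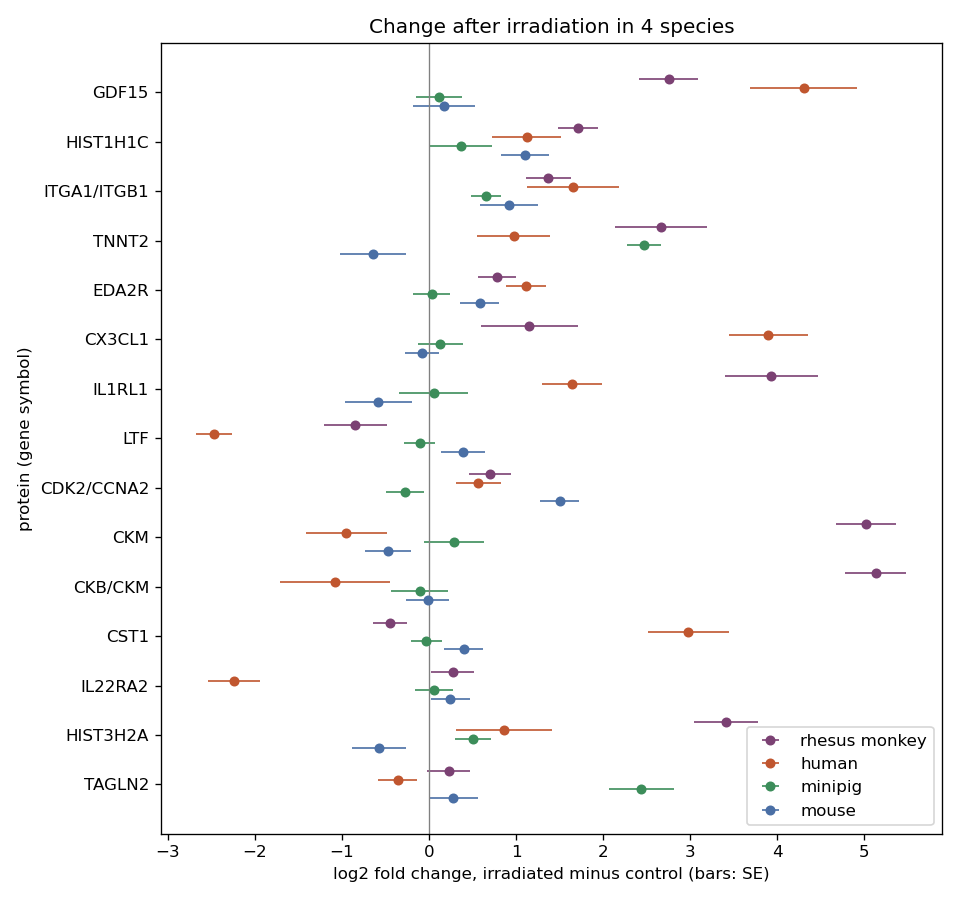
Log2 fold change, irradiated minus control, of the 15 proteins with the smallest p in the joint tests, with 1 point per species and bars for ±1 SE. CKM stood at 5.02 in monkey and −0.95 in human, and GDF15 at 2.75 in monkey, 4.31 in human, 0.12 in minipig and 0.17 in mouse.

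The similarity of whole responses did not pass the test against regrouped samples for any of the 6 pairs of species. These regroupings did not keep the monkey samples in their pairs of consecutive numbers. Across the 1305 aptamers, which are not independent replicates, log2 fold changes of monkey and human had a Spearman correlation of 0.360 and a Pearson r of 0.266 (permutation p = 0.05 and 0.14, adjusted over the 6 pairs 0.3 and 0.75). The Spearman correlation was 0.300 for monkey and minipig, 0.185 for human and minipig, −0.196 for monkey and mouse, −0.0811 for human and mouse and −0.0716 for minipig and mouse, with adjusted permutation p-values of 0.69 to 0.9, and Pearson r lay between −0.147 and 0.257. Without minipig irradiated replicate 1 it was −0.0604 for monkey and minipig and −0.102 for human and minipig. Of the 44 and 16 proteins that rose in monkey and human, 1 was shared, GDF15, against 0.539 for independent lists (one-sided Fisher's exact p = 0.424). No protein was among the 4 and 7 that fell in both.

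In the authors' deposited table for monkey 10 targets had an adjusted p under 0.05, with CKB/CKM, TKT, MDH1, H2AFZ, LDHB and GAPDH among them, and 327 a p under 0.05. CKM, IL1RL1 and GDF15 were not among the 10, with the authors' adjusted p at 0.0720, 0.0720 and 0.0982. The authors' deposited tables for human, minipig and mouse held 0 targets with an adjusted p under 0.05, and 174, 20 and 82 with a p under 0.05. The fold in the authors' deposited table was 4.46 for monkey CKM, where the RFU of the same 6 samples differed 40.9-fold. For human GDF15 the authors' deposited table gave 3.51 against 19.8-fold in RFU, and for human LTF 0.433 against 0.181. The slope of the authors' deposited table differences on log2 RFU differences was 0.408 in monkey, 0.437 in human, 0.381 in minipig and 0.370 in mouse.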

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

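Chosen only after the result was seen were the tests of red cell or platelet release, of a scaling factor and of red cell lysis below, the question of unirradiated day 1 samples, the comparison of irradiated replicate 4 with every control, the splits without both samples numbered 4, and the regroupings that kept the monkey pairs. Of 110 groups of 4 or 5 values checked, 11 held a sample set apart from the rest, and chance sets apart about 1 in 20 groups.

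Monkey irradiated replicate 4 accounted for 5 of the 11. Its median correlation with its group was 0.803 against 0.957 or more in the other monkey samples, a gap of 0.922 of the range. It was set apart for RTN4R (gap of 0.919 of the range), CRP (0.874), HBA1/HBB (0.933) and PRKCZ (0.896). Proteins of the red cell and platelet lists, 41 in all, had a median deviation of 1.48 log2 units from the other irradiated monkeys against −0.07 for all aptamers, higher than 99.99% of 10000 random lists. Release from blood cells in that sample may therefore contribute, whereas a scaling factor for the whole sample is argued against by the correlation of 0.803, which a factor leaves untouched. A control sample under an irradiated label is argued against only by the later comparison with every control. Of 145 proteins called in the other 6 samples, 71.7% lay nearer to the irradiated mean in it, against 10.3% in control replicate 4. This missed the bound of over 75% set beforehand, so that test alone left the question open. In the later comparison 83.4% lay beyond every control towards that mean, against 34.5% of them beyond the 3 other controls in control replicate 4. Release from blood cells could also lift proteins above every control, so this share alone does not settle the label. The signals of irradiated replicate 4 were 13899.8 RFU for CKM, 17473.8 RFU for IL1RL1 and 2388.3 RFU for GDF15, against at most 875.7, 4834.5 and 962.1 RFU in controls.

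The muscle proteins of irradiated monkeys were weighed against red cell lysis and handling. Lysis is argued against: without both samples numbered 4 hemoglobin differed by 0.043 ± 0.22 while CKM differed by 5.35 ± 0.27. Handling or sampling that differed between the draws could not be told apart from irradiation, since 0 unirradiated samples were labelled day 1. A biological source of muscle enzyme in plasma after irradiation stays an untested hypothesis.

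The 0 calls in minipig were weighed against sample number. Subsets of 2 against 2 monkey samples gave a median of 0.5 calls over 36 subsets (range 0 to 44, 18 with none). Fewer samples may therefore account for the 0, and a weaker response cannot be told apart from it. Weaker binding of aptamers with human target names was not tested and cannot be told apart either. Aptamers with a mean signal under 100 RFU numbered 90 in minipig and 338 in mouse, against 55 in monkey and 3 in human. Subsets of 4 against 2 monkey samples, nearer in size to mouse, which also had 0 calls with 5 against 2, gave a median of 58.5 calls over 6 subsets (range 3 to 153, 0 with none). In monkey samples that size therefore did not rule out calls. The self-test recovered 94.0% of 4-fold changes with mouse sample numbers and 86.6% with minipig sample numbers. It planted many changes at once, with noise independent between aptamers, so this recovery need not carry over. Minipig TNNI2 differed 8.14-fold and did not pass (limma, adjusted p = 0.196).

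Other samples set apart were monkey control replicate 3 for MDH1 (gap of 0.884 of the range), control replicate 4 for HIST1H1C (0.933) and FLT3LG (0.910), and control replicate 1 for CCL16 (0.870). Human irradiated replicate 4 was set apart for GNLY (0.846) and mouse control replicate 5 for SLC25A18 (0.719).

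The 10 proteins with the smallest p for unequal effects between species were CKM (adjusted p = 3.99e-07), CKB/CKM (3.22e-06), CST1 (0.000189), IL22RA2 (0.000320), IL1RL1 (0.00109), LTF (0.00143), GDF15 (0.00144), HIST3H2A (0.00206), CX3CL1 (0.00313) and TAGLN2 (0.00313), by limma. Species, dose and time of sampling changed together, and aptamer binding can differ with species.

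Other splits of the same samples were counted. For monkey 1 of 35 splits gave as many calls, the real one with 48 against at most 1. For human it was also 1 of 35, the real one with 23 against at most 1. That share is under 0.05 and is the smallest that 35 splits can give. It takes the human samples as exchangeable, and the labels do not say whether controls and irradiated samples shared people. If the monkey samples are paired, 8 splits part every pair as the real one does, too few for a share under 0.05. The highest other of these gave 0, and those that keep a pair gave at most 1. Without both samples numbered 4 the 10 splits are too few for a share under 0.05 (145 against at most 0). Regroupings within species that kept the monkey pairs gave as many calls in 2 of 100 for the mean effect (20 calls, highest other 32). For unequal effects it was also 2 of 100 (32 calls, highest other 37). Both shares are under 0.05, but the highest other exceeded the real count each time, so chance is not excluded. A change in any species can make such a share small, so it does not show that changes were shared or unequal. Regroupings that broke the pairs gave 1 of 100 (highest other 12) and 3 of 100 (highest other 53). The share was not under 0.05 for the list counts, so chance stayed open there. At least the real 1 list came from 13 of 35 monkey splits (highest other 3). At least the real 4 came from 12 of 35 human splits (highest other 6).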

How the results depend on the processing

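Chosen only after the result was seen were the settings without both monkey samples numbered 4, the standardized scale, and the pair term in list and joint tests. An animal term named by the labels was not run, since they name no animals. No called protein named in the report changed direction under any setting. A background level was not given in the sources used here, so what it limits was not analysed here. The cause of each change below was not tested, except that leaving out samples leaves fewer. Where 1 irradiated or control sample was left in minipig or mouse, it was assumed to vary like the rest of its species.

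Monkey calls (48) numbered 21 with median centring, 31 standardized, 102 with 1 fit for all 8 groups, 13 with the replicate block from paired numbers, 145 without both samples numbered 4, 361 with both changes, and 310 at an unadjusted p under 0.05. Human calls (23) numbered 47 in 1 fit and 154 unadjusted. Minipig calls (0) numbered 1 and 39, and mouse calls (0) 1 and 47. Unequal effects (32) fell to 17 without human samples. The block gave 22 calls and 5 lists in the mean effect (20 and 4 without it), 42 for unequal effects and an adjusted p of 0.00183 for the monkey leakage list.

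With an estimated correlation 0 lists passed in monkey, human and the mean effect: monkey leakage had an adjusted p of 0.0967, the 4 human lists 0.862, the mean lymphocyte list 0.462 and the other 3 mean lists 0.372. The human neutrophil list had 0.0883 with median centring and 0.0847 with quantile normalization, and median centring gave 1 mouse list.

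Leaving out each sample in turn gave 12 to 167 monkey calls, 6 to 17 human, 0 to 0 minipig, 0 to 4 mouse, 7 to 29 for the mean effect and 24 to 46 for unequal effects. Lists past the threshold numbered 1 to 1 in monkey, 3 to 8 in human, 0 to 1 in minipig, 0 to 1 in mouse and 3 to 6 in the mean effect. List adjusted p ranged from 5.59e-05 to 0.00800 for monkey leakage, and in human from 8.21e-05 to 0.00259 (lymphocyte), 2.03e-05 to 0.0196 (interferon), 0.00246 to 0.0278 (inflammatory) and 0.0194 to 0.0808 (neutrophil). In the mean effect they were 0.00368 to 0.0293 (DNA damage), 0.000343 to 0.0154 (leakage), 0.00169 to 0.0154 (hormones) and 0.00518 to 0.0501 (lymphocyte). The Spearman correlation of effects ranged from 0.236 to 0.406 for monkey and human, −0.0604 to 0.383 for monkey and minipig, −0.293 to 0.00576 for monkey and mouse, −0.102 to 0.276 for human and minipig, −0.127 to 0.0177 for human and mouse and −0.1503 to 0.0803 for minipig and mouse.

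Direction changed for values that had not passed. Without minipig irradiated replicate 1 minipig GDF15 was −0.15 and CKM −0.092 (0.39 and 0.67 without irradiated replicate 2), and the Spearman correlation was −0.0604 (monkey and minipig), −0.102 (human and minipig) and 0.0314 (minipig and mouse). Without mouse control replicate 1 it was 0.00576 (monkey and mouse), 0.0177 (human and mouse) and 0.0803 (minipig and mouse), the last 0.0150 without control replicate 2 and 0.0278 without irradiated replicate 1. Monkey FLT3LG was 0.080 without control replicate 4, −0.60 without irradiated replicate 1 and 0.28 without both numbered 4, with or without the block. Human FLT3LG was −0.089 (quantile), −0.20 (median), −0.031 (standardized), −0.26 without control replicate 2, 0.22 without control replicate 1, −0.03 without irradiated replicate 1 and −0.07 without irradiated replicate 4.

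Of the values of named proteins over all settings, 176 of 675 monkey values and 81 of 382 human values lost the call, 16 of 340 in the mean effect and 4 of 340 for unequal effects.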

Other observations

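The test of cystatins below was chosen only after the result was seen, and both list differences were planned before their own result was seen. Each list difference took up a list call made on these same samples, so it is not independent of that call. The proteins named in the next paragraph were chosen after their values were seen.

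Histone H2B type 2-E (HIST2H2BE) rose 4.04-fold in irradiated monkeys (2.02 ± 0.44, adjusted p = 0.0481) and histone H3.1 (HIST1H3A) 2.15-fold (1.10 ± 0.23, adjusted p = 0.0428), both higher in 4 of 4 irradiated samples than in any control, by limma. Neither passed with the pair term (adjusted p = 0.115 and 0.113). The protein kinases C zeta (PRKCZ) and delta (PRKCD) rose 3.35-fold and 2.03-fold (adjusted p = 0.0167 and 0.0334, and 0.0795 and 0.0765 with the pair term). Cystatin F (CST7), a protease inhibitor of immune cells, rose 2.62-fold in monkey (1.39 ± 0.19, adjusted p = 0.0095, and 0.0344 with the pair term).

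CST1 and CST2 are cystatins best known from saliva and other glandular secretions, which led to the hypothesis that salivary cystatins rise apart from the rest in human plasma. CST5 measured 2.73 ± 0.65 (adjusted p = 0.118) and CST4 0.79 ± 0.21 (adjusted p = 0.160), neither past the threshold, while CST3, CST6 and CST7 measured −0.09, −0.24 and 0.19. CST1 and CST2 prompted the question and were left out of its test. The difference between the medians of CST4 and CST5 and of the 3 other cystatins was 1.85 (exact two-sided permutation p = 0.0286 over 35 groupings of the samples, the smallest they can give). The source of these proteins and binding of an aptamer to a related cystatin were not analysed here, and the hypothesis was found and tested on the same samples. In monkey CST1 and CST2 measured −0.45 and 0.13.

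The lymphocyte list was tested for a different shift in human and monkey. It lay lower in human with the preset correlation (camera, adjusted p = 3.90e-05) but not with an estimated one (adjusted p = 0.126 with an estimated correlation), so the difference stayed open. The leakage list was higher in monkey than in mouse with the preset correlation (adjusted p = 0.00334), and the estimated correlation gave an adjusted p of 0.853, which also left it open.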
